A study of Mus musculus with 45 samples.

How the data were processed

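RNA was taken from perfused, frozen and powdered whole mouse hearts with an miRNeasy kit and sequenced after selection of polyadenylated RNA, per the labels' protocols. The submitters' processing notes name cutadapt, STAR, HTSeq and DESeq2 and the genome build GRCm38; their versions, settings and order, the annotation release, the read length and the strandedness of the library are not given in the sources used here. Groups and replicate numbers came from the sample titles, which give genotype, injury, number and time. All 45 libraries were assigned to 1 of 12 groups and each column of per-sample values was matched to its library by name.

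The authors deposited 2 tables, of 16 and 29 libraries, each listing 19432 genes. Per the file headers, the signal per gene and library is a normalized count, a read count divided by a factor per library, and each table was normalized on its own. The deposited log2 values are the authors' log2 fold changes between pairs of groups. The deposited p-values are adjusted p-values of the authors' model, by an adjustment not given in the sources used here. The deposited score per gene and pair equals the largest read count among the libraries compared. Other deposited values are the authors' limits for a call, an adjusted p of at most 0.05, a fold of at least 1.5 and a largest count of at least 30. Results of the authors' tables are named as such; all other values were computed here from the normalized counts. Of the listed genes, 16 in the first and 67 in the second experiment were at 0 in all libraries, and 11 symbols were shared by 2 gene identifiers, which were kept apart. Gene positions came from GENCODE M21 (GRCm38), in which 19390 of the gene identifiers were found, 18865 with the same symbol and 15567 as protein coding.

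Because the deposited values are rounded to 2 decimals, the read behind each step could be recovered: in every library 100% of values were whole multiples of the value of 1 read within a tolerance of 0.1 reads, the largest distance being 0.0058. In 2 libraries, WT sham T3 replicate 3 and WT MI T3 replicate 2, the factor was so close to 1 that low values alone could not tell the step from whole numbers. The recovered reads summed to 14199741 to 19015856 per library. This depth sets counting error only for genes of low count, and the precision of a comparison was set mostly by the spread between hearts. No library pair of a group agreed within sampling noise; the lowest chi-square per gene among 63 replicate pairs was 4.41.

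The tests fixed before the data were examined assumed raw counts and named limma as the test for any other unit. The values being normalized, limma's trend method with robust empirical Bayes moderation was applied to log2(normalized count + 1), with a mean for each group and all groups of a table in the fit. Genes entered where the value was at least 10 in at least as many libraries as the smallest group. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and genes under 0.05 were called. For each time the comparisons were OE against WT in sham and in MI, MI against sham in WT and in OE, and the interaction of both. The effect of OE at T3 minus that at T2 was tested in the second table. For T3 minus T1 the reads of both tables were scaled jointly, since the tables were normalized separately. There were 19 comparisons. Genes called at T1 and again in the same direction later were counted among genes tested at both times.

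A total of 26 gene lists were fixed before the files were seen, from textbook knowledge of heart muscle, ERBB signalling, metabolism, growth, stress and the other cell types of the heart. Each was tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated per list, and with limma's fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of called members are given over all genes and after adjustment over the list alone. Of the list members, Fgf21 and Ly6g were not analysed here.

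Genes named in the text followed a rule fixed with the tests. It takes a fixed set of markers (Erbb2, Nppa, Nppb, Myh6, Myh7, Acta1, Ankrd1, Runx1, Mki67, Cpt1b, Col1a1, Postn, Cd68, Nqo1) at every time in sham hearts. For OE against WT, and MI against sham in WT, it takes up to 5 called genes each way with the largest fold change, a mean CPM of at least 8, no overlap between libraries and no symbol of a predicted gene. It also takes up to 3 called members per list with the smallest p, up to 5 genes each way with the smallest p for interactions and differences between times, and up to 5 each way that were called at T1 and again at T3. Atrial genes, Kcnip2 at T1, Inmt in sham hearts at T3, the T3 interaction of Nppa, the genes near Rps2, Ankrd63 in the T1 interaction, and Ret, Nos2, Etl4 and Kalrn in OE hearts after MI were chosen after their values were seen.

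The limma analysis was tested on simulated data, with 200 genes changed by known folds in counts drawn from the means and depths of the real libraries. Of genes changed 2-fold it recovered 70.8% in OE against WT sham at T1, 82.1% at T2 and 76.9% at T3, and 71.6%, 69.2% and 80.3% in MI. For MI against sham it recovered 66.2%, 73.8% and 84.8% in WT and 62.1%, 69.7% and 72.3% in OE. For the interactions it recovered 43.9%, 54.5% and 63.6%, and for T3 minus T2 and T3 minus T1 69.7% and 65.2% in sham and 62.7% and 71.9% in MI, in no case with the wrong direction.

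Alternatives fixed with the tests were DESeq2 on the recovered reads, no filter on low values, a call rule with at least a 2-fold change, a fit of the compared groups alone, a replicate block, removal of mitochondrially encoded genes before scaling, and leaving out each library in turn. The edgeR quasi-likelihood test on the recovered reads, TMM scaling, scaling by library totals, a pseudocount of 8, a covariate for atrial genes and the removal of 2 libraries were added after the data were seen. Other splits of the libraries into groups of the same sizes were drawn, up to 100 for each result. Genes with near-identical copies, such as Rps2, and overlapping genes are uncertain, since the counting of shared reads is not given in the sources used here. Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.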

Results

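Gene expression was measured by RNA sequencing in 45 libraries of mouse heart, each from RNA of a whole perfused heart. The hearts fell into 12 groups by transgene, injury and time. Wild-type hearts (WT) were set against hearts carrying a transgene for transient overexpression, in cardiomyocytes, of ERBB2 (OE), a receptor tyrosine kinase that pairs with other ERBB receptors bound to neuregulin. Hearts of each genotype had sham treatment or the injury labelled MI; the series title speaks of ischemic injury. They were taken during the overexpression (T1), 2 weeks after it (T2) or 4 weeks after it (T3), when cardiomyocytes that had dedifferentiated are described as redifferentiating. Each group held 4 libraries, except OE MI T2, WT MI T2 and OE sham T3 with 3 each. The 16 libraries of T1 formed a first experiment and the 29 libraries of T2 and T3 a second. Depth was 14199741 to 19015856 reads assigned to genes per library. When the injury was made relative to the overexpression and the harvest is not given in the sources used here. No label says more than that the libraries of a group are separately numbered, so p-values measure the spread between these samples.

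Erbb2 (chromosome 11, 98412470 to 98437716 in GRCm38, plus strand, protein coding) checked the labels. Its normalized read count was 246 ± 3.3 (SD, n = 4) in WT sham and 1697 ± 692 (n = 4) in OE sham at T1, and every OE sham library, from 769.7 to 2436.2, lay above every WT library. In the injured hearts of T1 it was 247 ± 48.8 in WT and 1494 ± 729 in OE, where the 4 libraries ran from 768.8 to 2401.4. At T2 the sham means were 203 ± 21 and 283 ± 16.9 (n = 4 each), and the MI means 237 ± 10.7 and 288 ± 32.2 (n = 3 each). At T3 they were 204 ± 22 in WT sham (n = 4), 237 ± 2.55 in OE sham (n = 3), 200.4 ± 15.4 in WT MI and 233 ± 18.7 in OE MI (n = 4 each). The log2 fold change of OE over WT in sham was 2.67 ± 0.34 (SE) at T1 (limma adjusted p = 2.01e-05), 0.48 ± 0.09 at T2 (limma adjusted p = 0.000259) and 0.22 ± 0.10 at T3 (limma adjusted p = 0.141). In MI it was 2.48 ± 0.34, 0.28 ± 0.10 and 0.22 ± 0.09, with limma adjusted p of 0.000109, 0.207 and 0.205. Reads of the construct enter this count only as far as it matches mouse Erbb2.

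**Figure D1:**
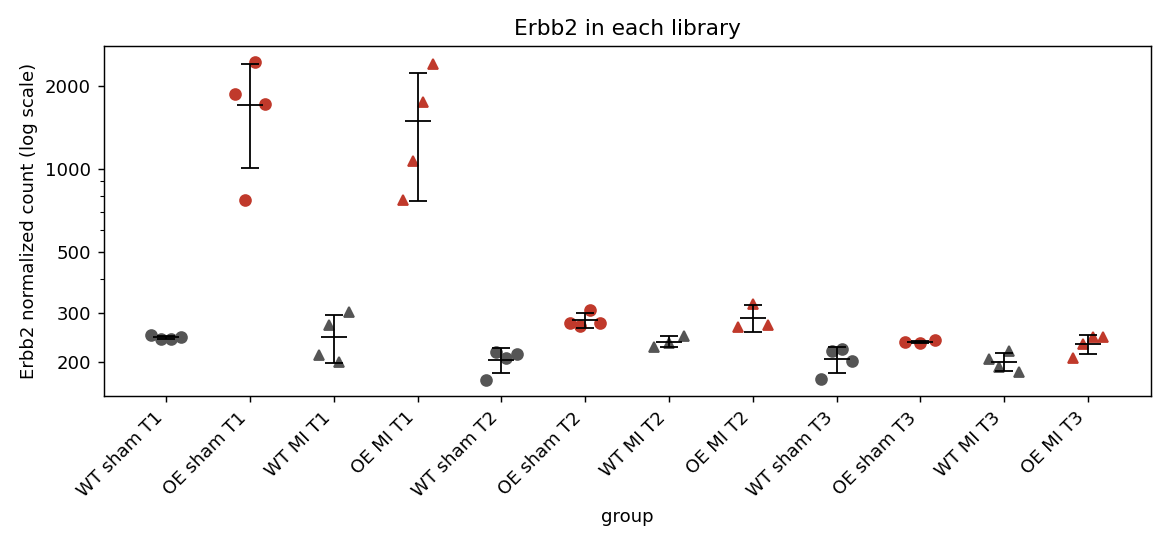
Normalized read counts of Erbb2 in each of the 45 libraries (log axis), grouped by time, with WT in grey and OE in red, circles for sham and triangles for MI; bars are means ± SD. All 8 OE libraries of T1 lie at or above 768.8, above every WT library.

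Values given below after a gene's name are log2 fold changes ± SE on the log2(normalized count + 1) scale, which understates changes of low genes, and the words rose and fell are used only of genes or gene lists that passed limma's test at an adjusted p under 0.05. The deposited values carry a scaling of the authors. Scaling the same reads by library totals instead, an alternative chosen after the data were seen, moved the median log2 fold change of all genes most in OE against WT sham at T1, from 0.0145 to 0.32. With library totals it was 0.28 in OE against WT MI at T1, 0.08 for MI in WT at T1, 0.22 in OE against WT sham at T2, 0.13 for MI in WT at T2, -0.14 for the interaction of T2, 0.18 and 0.15 for MI at T3 in WT and OE, and -0.12, -0.21 and -0.19 for the differences between times described last. Changes are therefore relative to the deposited scaling, and counts by library totals are given for all genes and for lists where they differed by over 1.5 times and at least 3 genes.

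**Figure D2:**
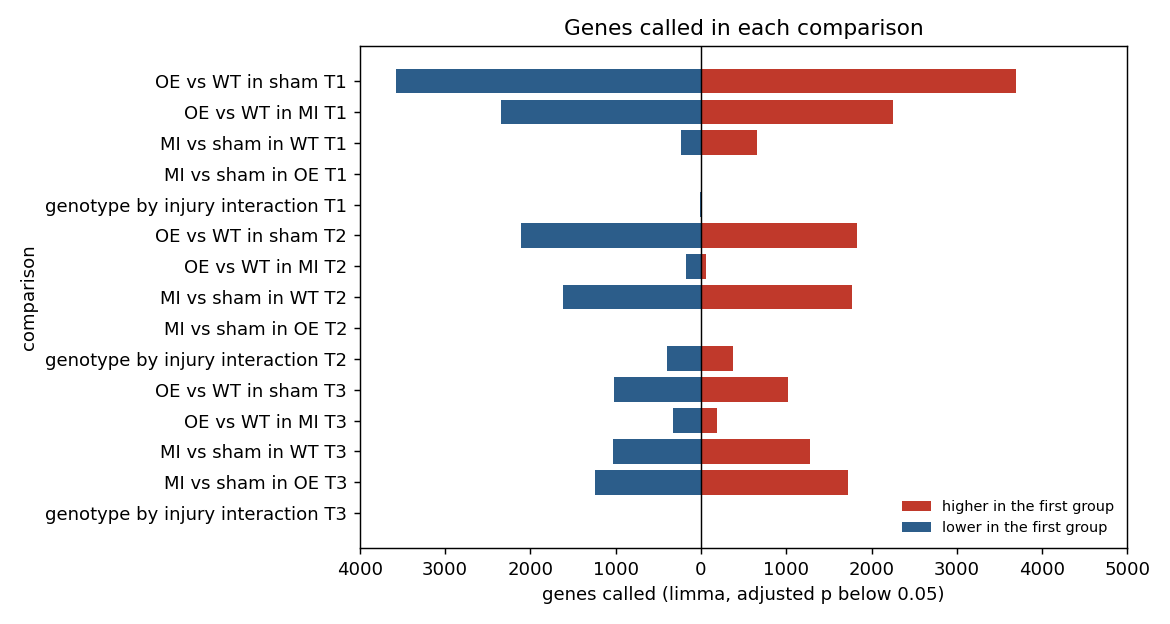
Number of genes called higher and lower in each comparison (limma, adjusted p under 0.05). OE against WT sham hearts gave 3692 higher and 3579 lower genes at T1, 1834 and 2109 at T2, and 1016 and 1020 at T3.

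The first question was what the overexpression changed in uninjured hearts. During it (OE against WT sham at T1, n = 4 each), the natriuretic peptide genes Nppa and Nppb, stress markers of the heart, rose by 2.94 ± 0.34 and 3.21 ± 0.41. The stretch-response gene Ankrd1 rose by 2.03 ± 0.35. Myh6, the main adult myosin heavy chain of the mouse heart, fell (-1.03 ± 0.13), and Myh7, its fetal counterpart, rose (0.95 ± 0.35). The skeletal actin gene Acta1 was at 0.50 ± 0.58 (limma adjusted p = 0.502). The transcription factor gene Runx1 rose by 1.68 ± 0.31 and the proliferation marker Mki67 by 1.89 ± 0.28. The matrix genes Col1a1 and Postn rose by 2.97 ± 0.28 and 3.64 ± 0.19, which for Col1a1 was 2513 ± 542 normalized counts (SD) in WT and 19617 ± 3013 in OE. The macrophage marker Cd68 rose by 0.69 ± 0.24, while Cpt1b, which brings fatty acids into mitochondria, and the antioxidant enzyme gene Nqo1 fell (-0.91 ± 0.12 and -0.55 ± 0.16). Among genes with no overlap between the libraries, the largest increases were those of F2rl2 (8.65 ± 0.71), Frem1 (5.74 ± 0.29), Sprr1a (5.09 ± 0.94), the matrix glycoprotein gene Tnc (4.88 ± 0.41) and Cilp (4.83 ± 0.35). The largest decreases were those of Efnb3 (-4.78 ± 0.52), the chloride channel gene Clcn1 (-4.30 ± 0.47), Lrrc15 (-3.98 ± 0.43), Pfkfb1 (-3.98 ± 0.32) and Lrtm1 (-3.97 ± 0.34).

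Genes of energy metabolism fell together at T1. Of 26 genes of oxidative phosphorylation 26 fell (0 and 26 adjusted over the list alone), among them Cox7a1 (-1.44 ± 0.10), Ndufs1 (-1.10 ± 0.09) and Uqcrc1 (-1.02 ± 0.07). As a set, the 26 genes had adjusted p = 1.84e-17 in limma's camera and adjusted p = 0.141 with an estimated correlation. Of 26 genes of fatty acid oxidation 25 fell (0 and 25 adjusted over the list alone; Eci1 -1.67 ± 0.13, Etfb -1.33 ± 0.10). For this list limma's camera gave adjusted p = 2.07e-15, and adjusted p = 0.141 with an estimated correlation. All 19 genes of the tricarboxylic acid cycle fell (0 and 19 adjusted over the list alone; Suclg2 -1.41 ± 0.11). Over these 19 genes limma's camera gave adjusted p = 6.53e-15, and adjusted p = 0.141 with an estimated correlation. In glycolysis and the pentose phosphate pathway 10 of 23 genes rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.056 in limma). The platelet-type phosphofructokinase gene Pfkp rose (2.16 ± 0.26), as did the lactate exporter gene Slc16a3 (2.70 ± 0.32). The muscle type Pfkm fell (-1.07 ± 0.12). The contractile and calcium genes fell as well. Of 22 adult sarcomere genes 2 rose and 14 fell (2 and 14 adjusted over the list alone; Tnni3 -1.23 ± 0.09, Myl2 -1.16 ± 0.10, Myl3 -1.35 ± 0.12). Tested together, the 22 genes had adjusted p = 8.85e-05 in limma's camera and adjusted p = 0.245 with an estimated correlation. Of 24 genes of calcium handling and ion channels 18 fell (0 and 18 adjusted over the list alone), including the calcium pump gene Atp2a2 (-1.76 ± 0.15), Hrc (-1.78 ± 0.16) and Jph2 (-0.90 ± 0.07). The list's adjusted p was 4.06e-08 in limma's camera and adjusted p = 0.0927 with an estimated correlation. With library totals 5 sarcomere genes rose and 10 fell (median -0.15 in place of -0.45), 3 calcium genes rose and 17 fell, and in glycolysis 15 rose and 1 fell.

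Lists of growth signalling and of tissue remodelling moved the other way. Among targets of the ERK pathway, which ERBB receptors feed, 20 of 22 rose (20 and 0 adjusted over the list alone; Phlda1 3.04 ± 0.21, Spred1 1.47 ± 0.09, Etv5 1.77 ± 0.17). In limma's camera the 22 genes had adjusted p = 2.37e-09, and adjusted p = 0.0821 with an estimated correlation. Fetal and dedifferentiation markers counted 16 higher and 1 lower of 25 (16 and 1 adjusted over the list alone). Compared with other genes, these 25 had adjusted p = 3.87e-05 in limma's camera and adjusted p = 0.0927 with an estimated correlation. In the cell cycle list 23 of 30 rose and 1 fell (23 and 1 adjusted over the list alone; Ccna2 2.20 ± 0.28, Ccnd1 1.35 ± 0.16, Tyms 1.60 ± 0.22). With all 30 genes limma's camera gave adjusted p = 6.27e-08, and adjusted p = 0.245 with an estimated correlation. Fibroblast and matrix genes rose in 23 of 24 cases (23 and 0 adjusted over the list alone; Mmp2 2.40 ± 0.13). Camera in limma gave these 24 genes adjusted p = 2.07e-15, and adjusted p = 0.0821 with an estimated correlation. Genes of mesenchymal transition rose in 18 of 22 (19 and 0 adjusted over the list alone; Mmp14 2.89 ± 0.23). Against all other genes, this list had adjusted p = 3.67e-10 in limma's camera and adjusted p = 0.0821 with an estimated correlation. Of 21 macrophage and monocyte markers 12 rose and 1 fell (13 and 1 adjusted over the list alone). As a set, the 21 genes had adjusted p = 0.0329 in limma's camera and adjusted p = 0.57 with an estimated correlation. Lgals3 (2.16 ± 0.44) and Adgre1 (0.92 ± 0.19) rose and Timd4, a marker of resident macrophages, fell (-0.90 ± 0.22).

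The other lists did not pass limma's camera at T1 in sham hearts. Of the 14 ERBB receptors and ligands 6 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.31), with the ligand gene Hbegf at 2.92 ± 0.30 and the receptor gene Egfr at 1.54 ± 0.21. YAP and TEAD targets counted 7 higher and 3 lower of 19 (7 and 3 adjusted over the list alone), and genes of the unfolded protein and ATF4 response 11 and 4 of 21 (12 and 4 adjusted over the list alone; Mthfd2 2.14 ± 0.26, Pycr1 2.15 ± 0.22, Herpud1 -1.40 ± 0.18). Antioxidant genes counted 8 and 11 of 29 (8 and 11 adjusted over the list alone; Gstm1 -1.53 ± 0.15, Sod2 -1.11 ± 0.09). Cell cycle arrest and p53 targets counted 9 higher and 3 lower of 17 (10 and 4 adjusted over the list alone; Phlda3 1.41 ± 0.19, Ccng1 -1.19 ± 0.11) and interferon response genes 4 and 0 of 20 (2 and 0 adjusted over the list alone; Cxcl10 2.26 ± 0.35). Among markers of other cells, 0 of 11 lymphocyte genes rose and 0 fell (0 and 0 adjusted over the list alone), against 0 and 1 of 6 for neutrophils (Lcn2 -1.17 ± 0.35), 1 and 4 of 18 for endothelium (Tek -0.48 ± 0.14), and 3 and 2 of 14 for mural cells (Cspg4 1.68 ± 0.16). The counts were 2 and 2 of 12 for epicardium (Muc16 -1.43 ± 0.42), 0 and 1 of 10 for adipocytes (Plin4 -1.08 ± 0.23), 1 and 3 of 10 for Schwann cells (Kcna1 -1.33 ± 0.25) and 0 and 5 of 6 for erythroid cells (Alas2 -1.68 ± 0.40, Hbb-bs -1.47 ± 0.53). Adjusted over the list alone these counts were 0 and 0, 0 and 1, 1 and 3, 3 and 2, 2 and 2, 0 and 1, 1 and 3, and 0 and 5. The medians of the antioxidant, neutrophil, endothelial, mural, adipocyte and Schwann lists lay below 0 and turned above 0 with library totals, that of the antioxidant list also with TMM scaling. With library totals 13 YAP targets (0 lower), 15 genes of the unfolded protein response (1 lower) and 12 interferon genes were higher, 13 antioxidant genes were higher and 8 lower, 5 endothelial markers were higher and 0 lower, and 1 erythroid marker was lower.

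In all, limma called 3692 genes higher and 3579 lower of 15375 at T1 in sham hearts, 2101 of them with at least a 2-fold change. With library totals the split was 7166 higher and 1782 lower, 80.1% against 50.8% of calls higher. Mitochondrially encoded transcripts made up 17.8% of reads in OE sham and 26.1% in WT sham. The authors' deposited table, with its own thresholds of fold and depth, lists 1928 higher and 1923 lower genes for this pair.

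In injured hearts at T1 (OE against WT MI, n = 4 each) Nppa rose by 2.54 ± 0.34, Ankrd1 by 1.58 ± 0.35, Mki67 by 1.77 ± 0.28 and Postn by 1.82 ± 0.19. The largest increases with no overlap were F2rl2 (6.02 ± 0.71), Frem1 (4.70 ± 0.29), Sprr1a (4.11 ± 0.94), Serinc2 (3.26 ± 0.59) and the early growth response gene Egr2 (3.21 ± 0.55). The largest decreases were those of the adrenergic receptor gene Adra1a (-3.21 ± 0.42), Efnb3 (-3.21 ± 0.52), Pfkfb1 (-3.13 ± 0.32), Lrrc15 (-3.07 ± 0.43) and Lrtm1 (-2.96 ± 0.34). All 26 of 26 genes of oxidative phosphorylation fell (0 and 26 adjusted over the list alone; Cox7a1 -1.53 ± 0.10). For this list limma's camera gave adjusted p = 1.85e-24, and adjusted p = 0.103 with an estimated correlation. Fatty acid oxidation fell in 25 of 26 (Eci1 -1.50 ± 0.13, Acadvl -1.14 ± 0.11) and the tricarboxylic acid cycle in 19 of 19 (Suclg2 -1.24 ± 0.11), both the same adjusted over the list alone, with limma camera adjusted p of 5.46e-20 and 3.51e-19 and adjusted p = 0.103 for both with an estimated correlation. Of 24 calcium and channel genes 1 rose and 18 fell (1 and 18 adjusted over the list alone; Atp2a2 -1.49 ± 0.15). Over these 24 genes limma's camera gave adjusted p = 4.37e-08, and adjusted p = 0.103 with an estimated correlation.

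ERK targets rose in 16 of 22 cases in the same pair of groups (19 and 0 adjusted over the list alone; Phlda1 1.66 ± 0.21, Spry4 1.49 ± 0.23). Tested together, the 22 genes had adjusted p = 7.25e-09 in limma's camera and adjusted p = 0.103 with an estimated correlation. Cell cycle genes rose in 22 of 30 and fell in 1 (25 and 1 adjusted over the list alone; Ccna2 1.73 ± 0.28, E2f1 1.35 ± 0.20). The list's adjusted p was 5.42e-10 in limma's camera and adjusted p = 0.192 with an estimated correlation. For fibroblast and matrix genes the counts were 17 higher and 0 lower of 24 (17 and 0 adjusted over the list alone; Mmp2 1.13 ± 0.13, Col8a1 2.18 ± 0.23). In limma's camera the 24 genes had adjusted p = 1.23e-09, and adjusted p = 0.129 with an estimated correlation. Lymphocyte markers rose in 5 of 11 (5 and 0 adjusted over the list alone; Lck 3.03 ± 0.60, Cd3e 2.74 ± 0.84, Trac 1.36 ± 0.46; limma camera adjusted p = 0.105). Macrophage markers counted 0 higher and 1 lower of 21, the lower being Timd4 (-1.21 ± 0.22). Limma called 2256 genes higher and 2344 lower, against 6289 and 1137 with library totals; the authors' deposited table lists 1058 and 1155.

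The response to the injury was then compared within each genotype. In WT hearts at T1 (n = 4 each) matrix genes led it, with increases of Sfrp2 (3.62 ± 0.48), Tnc (2.89 ± 0.41), the collagen cross-linking enzyme gene Lox (2.65 ± 0.37), Cilp (2.41 ± 0.35) and elastin, Eln (2.41 ± 0.35). Decreases included those of the clock gene Ciart (-1.36 ± 0.36), Entpd5 (-0.73 ± 0.20), Pde4a (-0.65 ± 0.16), Magi3 (-0.64 ± 0.15) and Phyhip (-0.63 ± 0.15). Of 24 fibroblast and matrix genes 19 rose (23 and 0 adjusted over the list alone; Postn 1.96 ± 0.19, Col3a1 2.21 ± 0.23). Compared with other genes, these 24 had adjusted p = 4.78e-27 in limma's camera and adjusted p = 0.0341 with an estimated correlation. Macrophage markers rose in 9 of 21 (15 and 0 adjusted over the list alone; Lyz2 1.34 ± 0.28, Adgre1 0.96 ± 0.19, C1qb 0.76 ± 0.14). With all 21 genes limma's camera gave adjusted p = 1.03e-10, and adjusted p = 0.167 with an estimated correlation. Of 26 genes of oxidative phosphorylation 1 fell (0 and 16 adjusted over the list alone; Uqcrc1 -0.28 ± 0.07). Camera in limma gave these 26 genes adjusted p = 2.43e-09, and adjusted p = 0.291 with an estimated correlation. Limma called 662 genes higher and 229 lower, against 1151 and 28 with library totals. The number was 1555 in all by DESeq2 and 490 when only the compared groups were fitted. Of 891 calls, 282, 385 and 531 were left in number without WT sham replicates 2, 4 and 1, 286, 501 and 552 without WT MI replicates 3, 4 and 2, and 1706 without WT MI replicate 1.

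In OE hearts at T1 limma called 0 genes higher and 1 lower after MI (n = 4 each), the receptor gene Ret (-0.93 ± 0.12), while 1534 genes had an unadjusted p under 0.05, DESeq2 called 104 (78 higher and 26 lower) and the edgeR test 1, and the authors' deposited table lists 69 higher and 10 lower. The limma count was 0 with only the compared groups in the fit, with a replicate block and without any of OE sham replicates 1 to 3 or OE MI replicate 3, 3 without OE MI replicate 4 and 40 without OE MI replicate 2. No member of any list was called over all genes. Adjusted over the list alone, 7 of 11 lymphocyte, 4 of 6 neutrophil and 4 of 12 epicardial markers were higher, with limma camera adjusted p of 4.84e-08, 2.54e-05 and 2.54e-05, and adjusted p of 0.221, 0.221 and 0.486 with an estimated correlation. The difference between genotypes in the response to MI was tested as an interaction. The response was lower in OE for Postn (-1.81 ± 0.27), the protease gene Ctsk (-1.60 ± 0.19), Mmp2 (-1.27 ± 0.19), Eno2 (-2.84 ± 0.44) and Ret (-1.09 ± 0.17), and higher for Satb1 (0.98 ± 0.16) and Ankrd63 (1.47 ± 0.26). Fibroblast and matrix genes had a median interaction of -1.07, with 4 of 24 lower (0 and 22 adjusted over the list alone) and adjusted p = 3.29e-28 by limma's camera and adjusted p = 0.0291 with an estimated correlation. Mesenchymal genes counted 1 of 22 lower (0 and 10 adjusted over the list alone). Against all other genes, this list had adjusted p = 3.12e-11 in limma's camera and adjusted p = 0.0339 with an estimated correlation. The interaction was called for 2 genes higher and 12 lower in limma, for 148 by DESeq2 and for 9 with library totals, none of them higher. Its 14 calls were 3, 2, 22 and 3 without WT sham replicates 1 to 4, 30, 56, 3 and 3 without WT MI replicates 1 to 4, 2, 4 and 3 without OE sham replicates 1 to 3, and 22, 23 and 2 without OE MI replicates 1 to 3.

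A question set by the design was what remained after the overexpression ended. At T2 in sham hearts (n = 4 each) Nppa was at 0.82 ± 0.41, Nppb at 1.17 ± 0.46, Myh7 at -1.06 ± 0.61, Acta1 at 0.21 ± 0.55, Mki67 at 0.58 ± 0.47 and Cd68 at -0.27 ± 0.17, none of them called (limma adjusted p of 0.152, 0.0654, 0.222, 0.83, 0.401 and 0.24), though Nppb passed with library totals or without WT sham replicate 1 and Nppa with a covariate for atrial genes. Ankrd1 (1.10 ± 0.24), Runx1 (0.79 ± 0.29), Col1a1 (0.91 ± 0.23) and Postn (1.03 ± 0.27) were higher, and Myh6 (-0.50 ± 0.11), Cpt1b (-0.29 ± 0.09) and Nqo1 (-0.68 ± 0.13) lower. The largest increases with no overlap were the matrix genes Cilp (3.19 ± 0.43), Thbs4 (3.08 ± 0.40) and Mfap4 (1.89 ± 0.34), with Inmt (2.56 ± 0.23) and Pamr1 (2.29 ± 0.31). The largest decreases were the carboxylesterase gene Ces1d (-2.37 ± 0.26), Lrrc4b (-2.17 ± 0.36), Mylk4 (-2.11 ± 0.15), Pfkfb1 (-2.04 ± 0.31) and the lipoxygenase gene Alox5 (-1.95 ± 0.18). Kcnip2 (chromosome 19, 45791839 to 45816061, minus strand), a subunit of the channel of the transient outward potassium current, was lower at every time, at -3.50 ± 0.37 at T1, -1.82 ± 0.14 at T2 and -2.13 ± 0.15 at T3, with limma adjusted p of 3.95e-06, 4.11e-09 and 2.77e-09.

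Metabolic lists were still lower at T2. Of 26 genes of oxidative phosphorylation 26 fell (0 and 26 adjusted over the list alone; Uqcrc1 -0.57 ± 0.08), at a median of -0.48. As a set, the 26 genes had adjusted p = 1.1e-22 in limma's camera and adjusted p = 0.0918 with an estimated correlation. Fatty acid oxidation fell in 22 of 26 genes (Eci1 -0.91 ± 0.10, Hadha -0.89 ± 0.09, and the lipase gene Lpl at -1.16 ± 0.08) and the tricarboxylic acid cycle in 19 of 19 (Dld -0.49 ± 0.06), with limma camera adjusted p of 2.49e-18 and 3.87e-17 and adjusted p = 0.0918 for both with an estimated correlation; adjusted over the list alone 22 and 19 fell. Calcium and channel genes counted 14 lower of 24 (0 and 16 adjusted over the list alone; Atp2a2 -0.74 ± 0.10). For this list limma's camera gave adjusted p = 5.34e-08, and adjusted p = 0.0918 with an estimated correlation. Antioxidant genes counted 1 higher and 18 lower of 29 (1 and 18 adjusted over the list alone; Mt1 -0.92 ± 0.12, Prdx1 -0.53 ± 0.07, Sod2 -0.45 ± 0.07). Over these 29 genes limma's camera gave adjusted p = 1.72e-05, and adjusted p = 0.0918 with an estimated correlation. Sarcomere genes counted 1 higher and 10 lower of 22 (2 and 11 adjusted over the list alone; Tnni3 -0.60 ± 0.10, Tpm1 -0.58 ± 0.08). Tested together, the 22 genes had adjusted p = 0.00216 in limma's camera and adjusted p = 0.375 with an estimated correlation. With library totals the antioxidant list counted 5 higher and 8 lower at a median of -0.10 in place of -0.31, calcium genes 9 lower, and sarcomere genes 4 higher and 5 lower with the median turning from -0.18 to 0.02.

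Matrix and growth lists were higher at T2. Of 24 fibroblast and matrix genes 17 rose (18 and 0 adjusted over the list alone; Mmp2 1.70 ± 0.19, Dcn 0.95 ± 0.10). The list's adjusted p was 5.52e-11 in limma's camera and adjusted p = 0.148 with an estimated correlation. ERK targets counted 11 higher and 1 lower of 22 (11 and 2 adjusted over the list alone; Dusp4 1.49 ± 0.24, Etv5 1.06 ± 0.18). In limma's camera the 22 genes had adjusted p = 0.000305, and adjusted p = 0.148 with an estimated correlation. Cell cycle genes counted 8 higher of 30 (10 and 0 adjusted over the list alone; Aurka 1.34 ± 0.31, Rrm2 1.25 ± 0.30). Compared with other genes, these 30 had adjusted p = 0.000873 in limma's camera and adjusted p = 0.528 with an estimated correlation. ERBB receptors and ligands counted 6 higher and 1 lower of 14 (6 and 2 adjusted over the list alone; Ereg 2.72 ± 0.48, Egfr 0.77 ± 0.17). With all 14 genes limma's camera gave adjusted p = 0.0477, and adjusted p = 0.111 with an estimated correlation. Macrophage markers counted 1 higher and 6 lower of 21 (1 and 10 adjusted over the list alone), the lower including the resident-macrophage markers Timd4 (-1.28 ± 0.27), Cd163 (-0.96 ± 0.20) and Lyve1 (-0.57 ± 0.15). Camera in limma gave these 21 genes adjusted p = 0.0174, and adjusted p = 0.651 with an estimated correlation. Limma called 1834 genes higher and 2109 lower of 15533 at T2; with library totals, which moved the median of all genes by 0.22, the split was 5184 and 758, with 13 cell cycle genes higher and 2 macrophage markers lower. The authors' deposited table lists 530 higher and 451 lower.

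**Figure D3:**
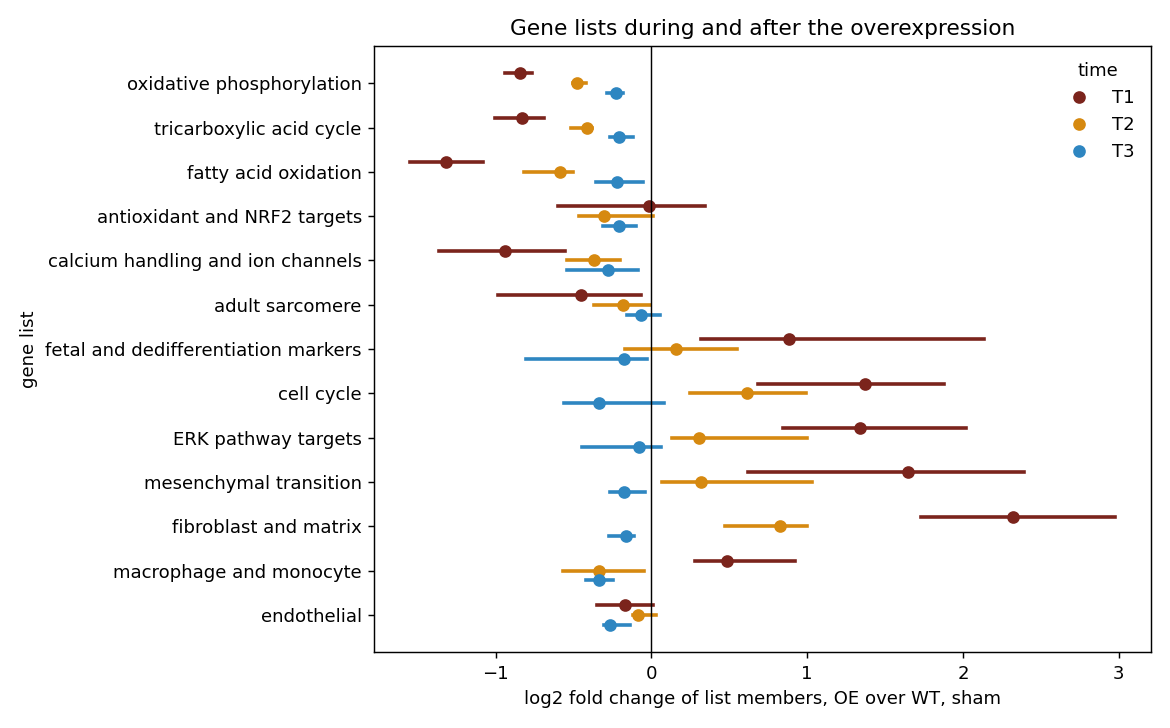
Gene lists in OE against WT sham hearts at T1, T2 and T3. Each dot is the median log2 fold change of a list's measured members and each line spans their quartiles, 25% to 75%; the median of oxidative phosphorylation was -0.84, -0.48 and -0.23, and that of fibroblast and matrix genes 2.32, 0.83 and -0.16.

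In injured hearts at T2 (OE against WT, n = 3 each) macrophage and matrix genes were lower. Macrophage markers fell in 6 of 21 cases over all genes (0 and 13 adjusted over the list alone; C1qc -1.02 ± 0.20, Cd68 -0.98 ± 0.19, Csf1r -0.75 ± 0.15). Against all other genes, this list had adjusted p = 1.45e-12 in limma's camera and adjusted p = 0.311 with an estimated correlation. Fibroblast and matrix genes had a median of -0.62 and 2 of 24 were lower (0 and 14 adjusted over the list alone; Fbn1 -0.99 ± 0.20, Col5a1 -0.63 ± 0.16). As a set, the 24 genes had adjusted p = 1.88e-10 in limma's camera and adjusted p = 0.311 with an estimated correlation. The largest increases with no overlap were Inmt, which encodes a methyltransferase (2.41 ± 0.27), Pdlim4 (1.24 ± 0.30), Lad1 (1.19 ± 0.29), Slc17a7 (1.17 ± 0.23) and Ifi207 (0.94 ± 0.21). Decreases were largest for the desaturase gene Scd4 (-3.02 ± 0.77), the sodium channel subunit gene Scn4b (-2.36 ± 0.46), Mylk4 (-1.81 ± 0.18), Lgi2 (-1.69 ± 0.36) and Angpt1 (-1.57 ± 0.30). Kcnip2 (-1.45 ± 0.16), Lpl (-0.61 ± 0.10), Gja1 (-0.69 ± 0.15) and Hmox1 (-0.79 ± 0.20) also fell, and the sarcomere gene Mybpc3 rose (0.44 ± 0.10). For oxidative phosphorylation 0 of 26 genes rose and 0 fell (limma camera adjusted p = 0.244). Limma called 63 genes higher and 179 lower, with 143 and 89 by library totals (3 macrophage markers lower), 452 in all by DESeq2 and 68 when only these groups were fitted. The 242 calls were 122 and 130 without WT MI replicates 2 and 3, and 109 and 70 without OE MI replicates 3 and 4; the authors' deposited table lists 27 higher and 185 lower.

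WT hearts at T2 had a broad response to MI (n = 3 against 4). Immunoglobulin genes rose (Ighg3 6.92 ± 1.85, Igkc 4.87 ± 1.07, Jchain 4.62 ± 1.07), as did Sfrp2 (5.09 ± 0.54) and the adipocyte gene Cfd (3.91 ± 1.09). Arrdc2 (-1.34 ± 0.32), Lrrc4b (-1.23 ± 0.39), Abca12 (-1.14 ± 0.29), Ano10 (-1.10 ± 0.19) and Vwa3a (-1.09 ± 0.28) fell. All 24 of 24 fibroblast and matrix genes rose (24 and 0 adjusted over the list alone; Cthrc1 4.66 ± 0.48, Timp1 3.15 ± 0.35, Fn1 2.48 ± 0.30). For this list limma's camera gave adjusted p = 3.66e-29, and adjusted p = 0.0456 with an estimated correlation. Oxidative phosphorylation fell in 24 of 26 genes (0 and 25 adjusted over the list alone; Ndufs1 -0.49 ± 0.08). Over these 26 genes limma's camera gave adjusted p = 2.92e-18, and adjusted p = 0.0996 with an estimated correlation. Fatty acid oxidation fell in 21 of 26 (0 and 23 adjusted over the list alone; Eci1 -0.68 ± 0.10) and the tricarboxylic acid cycle in 19 of 19 (0 and 19 adjusted over the list alone; Ogdh -0.48 ± 0.07), with limma camera adjusted p of 1.63e-14 and 4.2e-16 and adjusted p of 0.0996 and 0.0772 with an estimated correlation. Myh6 (-0.65 ± 0.11) and Hrc (-0.73 ± 0.11) fell, and Gdf15 (2.47 ± 0.48), the neuregulin gene Nrg1 (1.52 ± 0.33) and Ereg (3.05 ± 0.51) rose. Adipocyte markers moved in the same libraries, with 6 of 10 higher and 1 lower (9 and 1 adjusted over the list alone; Cidec 3.72 ± 1.10, Adrb3 3.97 ± 1.01). Tested together, the 10 genes had adjusted p = 0.00238 in limma's camera and adjusted p = 0.366 with an estimated correlation. Limma called 1766 genes higher and 1613 lower, with 2693 and 554 by library totals; the count was 2102 and 2117 without WT MI replicates 2 and 3, and 1629 when only these groups were fitted.

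In OE hearts at T2 the same comparison (n = 3 against 4) called 0 genes higher and 4 lower in limma, which were Vtn (-0.70 ± 0.10), Nos2 (-0.71 ± 0.13), Etl4 (-0.64 ± 0.12) and Kalrn (-0.42 ± 0.07). There were 1097 genes at an unadjusted p under 0.05, 37 called by DESeq2 (13 higher and 24 lower) and 4 by edgeR, and the authors' deposited table lists 8 higher and 14 lower. The limma count was 37 (22 higher and 15 lower, 2 of the 4 genes among them) with only the compared groups in the fit, 2 with library totals, 2, 1, 10 and 1 without OE sham replicates 1 to 4, and 2 and 1 without OE MI replicates 1 and 4. Fibroblast and matrix genes counted 0 higher over all genes (2 and 0 adjusted over the list alone). The list's adjusted p was 0.000128 in limma's camera and adjusted p = 0.566 with an estimated correlation. The interaction was called for 372 genes higher and 395 lower. Its lower members, with a smaller rise or a fall after MI in OE, included Timp2 (-1.06 ± 0.15), Bicc1 (-1.20 ± 0.17), Mxra8 (-1.11 ± 0.18), Marcks (-0.81 ± 0.13) and Lrrk1 (-0.86 ± 0.14), and 20 of 24 fibroblast and matrix genes (0 and 22 adjusted over the list alone). In limma's camera the 24 genes had adjusted p = 5.8e-25, and adjusted p = 0.0755 with an estimated correlation. Its higher members included Yipf7 (0.72 ± 0.12), Mgme1 (0.73 ± 0.13), Asb11 (0.66 ± 0.12), Mtfp1 (0.59 ± 0.10) and Mmaa (0.59 ± 0.11), and 20 of 26 genes of oxidative phosphorylation (26 and 0 adjusted over the list alone). Compared with other genes, these 26 had adjusted p = 1.55e-21 in limma's camera and adjusted p = 0.11 with an estimated correlation. With library totals the split was 71 higher and 627 lower, with 4 genes of oxidative phosphorylation higher at a median of 0.30 in place of 0.43, and DESeq2 called 1232. The 767 calls were 455 and 191 without WT MI replicates 2 and 3, 424 without OE sham replicate 2, and 75 and 415 without OE MI replicates 3 and 4.

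At T3, 4 weeks after the overexpression, Nppa (chromosome 4, 148000722 to 148002079, plus strand) was lower in OE sham hearts than in WT sham hearts by -3.41 ± 0.44 (limma adjusted p = 3.54e-05), with 861 ± 170 normalized counts (SD, n = 3) against 9768 ± 4386 (n = 4). Of the other fixed markers none was called in sham hearts at T3, Erbb2 (above) passing with library totals, Myh7 by DESeq2, Mki67 with only the compared groups and Acta1 without OE sham replicate 2. Values other than that of Erbb2 were -0.81 ± 0.49 for Nppb, -0.12 ± 0.11 for Myh6, -1.26 ± 0.66 for Myh7, 1.34 ± 0.59 for Acta1, -0.31 ± 0.26 for Ankrd1, -0.06 ± 0.32 for Runx1, -1.01 ± 0.51 for Mki67, -0.12 ± 0.10 for Cpt1b, -0.07 ± 0.25 for Col1a1, -0.19 ± 0.29 for Postn, -0.27 ± 0.18 for Cd68 and 0.09 ± 0.14 for Nqo1, with limma adjusted p from 0.143 for Acta1 to 0.935 for Runx1. Markers of atrial muscle were low in the same 3 libraries: 12 of 12 listed atrial genes were lower and 9 were called, among them Myl7 (-3.11 ± 0.72), Sbk3 (-2.65 ± 0.57) and Mybphl (-3.20 ± 0.72). Adipocyte and immunoglobulin genes were low as well (Cfd -4.00 ± 1.09, Adrb3 -3.53 ± 1.01, Lep -3.04 ± 1.0, Igkc -3.72 ± 1.07, Car3 -3.25 ± 1.07), with 3 of 10 adipocyte markers lower over all genes (0 and 9 adjusted over the list alone) and adjusted p = 4.85e-05 by limma's camera and adjusted p = 0.575 with an estimated correlation. Of 8 erythroid markers 0 were called over all genes (0 and 6 adjusted over the list alone). With all 8 genes limma's camera gave adjusted p = 0.00156, and adjusted p = 0.575 with an estimated correlation. The largest increases with no overlap were Padi2 (3.44 ± 0.54), the glutamate transporter gene Slc17a7 (2.21 ± 0.22), the skeletal calsequestrin gene Casq1 (1.97 ± 0.34), Mybpc2 (1.74 ± 0.26) and Gnb3 (1.53 ± 0.26).

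**Figure D4:**
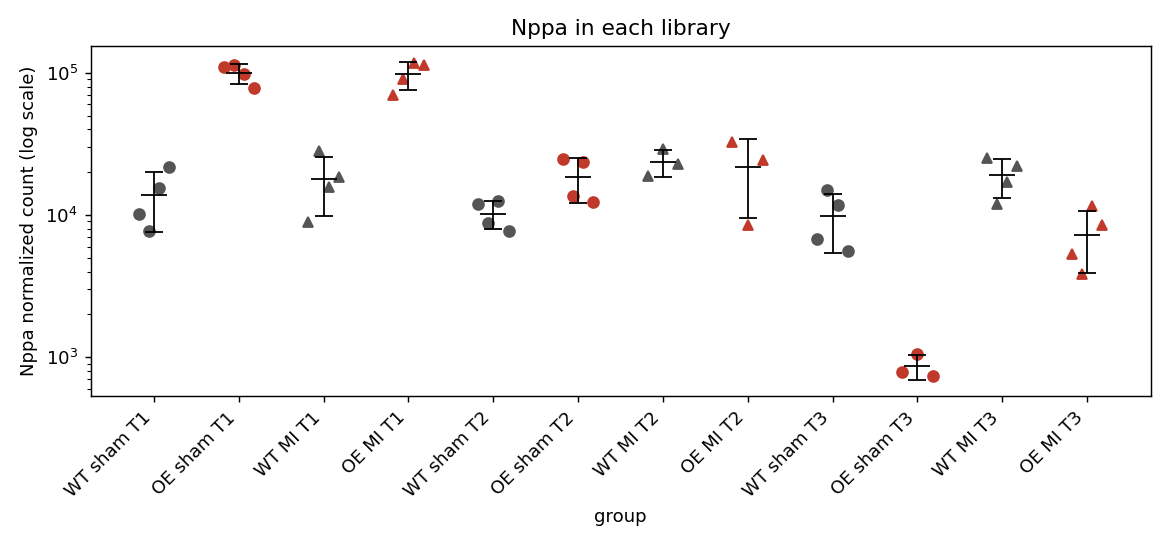
Normalized read counts of Nppa in each of the 45 libraries (log axis), grouped by time, with WT in grey and OE in red, circles for sham and triangles for MI; bars are means ± SD. OE sham means are 99448 at T1, 18553 at T2 and 861 at T3, against 13857, 10232 and 9768 in WT sham.

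Calcium, metabolic and endothelial genes were also lower at T3 in these libraries, in which the atrial markers were low. Calcium and channel genes counted 1 higher and 10 lower of 24 (1 and 15 adjusted over the list alone; Ryr2 -0.63 ± 0.12, Gja1 -0.86 ± 0.14). Camera in limma gave these 24 genes adjusted p = 4.06e-07, and adjusted p = 0.178 with an estimated correlation. Oxidative phosphorylation counted 15 lower of 26 (0 and 19 adjusted over the list alone; Sdhb -0.37 ± 0.08) at a median of -0.23. Against all other genes, this list had adjusted p = 1.74e-08 in limma's camera and adjusted p = 0.575 with an estimated correlation. The tricarboxylic acid cycle counted 8 lower of 19 (0 and 10 adjusted over the list alone), fatty acid oxidation 5 of 26 (1 and 6 adjusted over the list alone; Lpl -0.72 ± 0.09), antioxidant genes 6 of 29 (1 and 10 adjusted over the list alone; Mt2 -1.44 ± 0.27) and endothelial markers 7 of 18 (0 and 11 adjusted over the list alone; Vwf -0.62 ± 0.16), with limma camera adjusted p of 4.81e-05, 0.000657, 0.000273 and 4.81e-05 and, with an estimated correlation, adjusted p of 0.575, 0.575, 0.178 and 0.178. With library totals 3 genes of oxidative phosphorylation (median -0.13), 3 of the tricarboxylic acid cycle, 3 antioxidant and 1 endothelial were lower. Tpm1 (-0.84 ± 0.09), Gapdh (-1.04 ± 0.23), Eno1 (-0.52 ± 0.11), Ctgf (-1.28 ± 0.25) and Cd163 (-1.05 ± 0.22) fell and Cenpa rose (0.86 ± 0.11). Fibroblast and matrix genes counted 0 higher and 0 lower of 24 (0 and 0 adjusted over the list alone; limma camera adjusted p = 0.122). Limma called 1016 genes higher and 1020 lower, with 2018 and 545 by library totals; the authors' deposited table lists 219 and 403. The 2036 calls were 1345 without WT sham replicate 3, 1098 and 762 without OE sham replicates 1 and 3, 730 with the level of 4 atrial genes as a covariate and 14 with the OE MI T3 libraries also not in the fit, checks added after the data were seen.

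Genes called at T1 were then followed to the later times, in tables that share no library. In sham hearts 1182 of the genes higher and 1509 of those lower at T1 were called the same way at T2, 32.9% and 42.3% of the T1 calls, against 437.8 and 496.5 for independent lists of these sizes among the 15031 genes tested at both times; 104 were called the opposite way. At T3 it was 342 higher and 466 lower, 9.51% and 13.1% of the T1 calls, against 241.3 and 238 for independent lists (Fisher's exact test, one-sided p = 7.52e-14 and 4.37e-60, genes not being independent), while 141 turned from higher to lower and 195 from lower to higher, against 240.1 and 239.2. The 808 shared calls were 494 and 340 without OE sham T3 replicates 1 and 3, 1416 with library totals, 266 with the atrial covariate and 11 with the OE MI T3 libraries also not in the fit. The largest of those called at both T1 and T3 were Slc17a7, Tnfrsf12a (1.25 ± 0.27), the amino acid transporter gene Slc1a4 (1.22 ± 0.29), the calcium channel subunit gene Cacnb1 (1.18 ± 0.15) and Amot (1.14 ± 0.30) among the higher, and the ribosomal protein gene Rps2 (-4.63 ± 0.95), Myl7, Sbk3, the angiopoietin gene Angpt1 (-2.18 ± 0.28) and Art4 (-2.16 ± 0.62) among the lower; of these Slc1a4, Amot, Rps2, Myl7, Sbk3 and Art4 were not called at T2. Rps2 varied between libraries within other groups too, and has near-identical pseudogenes, so its value is uncertain. In injured hearts 25 higher and 70 lower genes were shared between T1 and T2, against 9.1 and 27.7, and 57 and 171 between T1 and T3, against 27.2 and 50. Those 95 calls of T2 were 59 and 54 without WT MI T2 replicates 3 and 4 and 59, 61 and 34 without OE MI T2 replicates 1, 3 and 4, 161 by DESeq2 and 29 with only the compared groups in the fit. The 228 of T3 were 149 without OE MI T3 replicate 1, 113 without the 2 OE MI T3 libraries low in atrial genes, 85 with only the compared groups, 116 with the atrial covariate and 378 with library totals.

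In injured hearts at T3 (OE against WT, n = 4 each) Kcnip2 was again lower (-2.10 ± 0.14, limma adjusted p = 1.36e-09), with Adra1a (-1.60 ± 0.28), Lrrc4b (-1.49 ± 0.36), Angpt1 (-1.48 ± 0.26) and Mylk4 (-1.41 ± 0.15). Inmt (2.35 ± 0.23), Slc17a7 (1.60 ± 0.20), Casq1 (1.31 ± 0.31), Lad1 (0.89 ± 0.25) and Apod (0.88 ± 0.22) were highest over WT. Ankrd1 (-0.98 ± 0.24), Tpm1 (-0.59 ± 0.08), Gja1 (-0.83 ± 0.13) and Timd4 (-1.21 ± 0.27) fell. Calcium and channel genes counted 6 lower of 24 (0 and 8 adjusted over the list alone; Jph2 -0.40 ± 0.07). As a set, the 24 genes had adjusted p = 4.85e-08 in limma's camera and adjusted p = 0.211 with an estimated correlation. Fetal markers counted 2 lower of 25 (0 and 6 adjusted over the list alone; Sox4 -0.88 ± 0.24). For this list limma's camera gave adjusted p = 4.85e-08, and adjusted p = 0.211 with an estimated correlation. Macrophage markers counted 2 lower of 21 (0 and 4 adjusted over the list alone; Csf1r -0.49 ± 0.13). Over these 21 genes limma's camera gave adjusted p = 5.15e-07, and adjusted p = 0.44 with an estimated correlation. The 4 atrial genes of the score averaged 9.52 ± 1.99 (log2, SD) in these OE hearts, of which 2 were low, against 11.10 ± 0.45 in WT. Limma called 186 genes higher and 324 lower, with 515 and 186 by library totals; the count was 316 and 299 without WT MI replicates 1 and 3, 325 without OE MI replicate 1, 160 when only these groups were fitted and 224 with the atrial covariate.

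The injury response of WT hearts at T3 (n = 4 each) again included matrix genes. Sfrp2 (3.28 ± 0.50), Wisp2 (2.77 ± 0.45), Comp (2.55 ± 0.52), Ltbp2 (2.50 ± 0.42) and Acta1 (2.13 ± 0.55) rose. Fmn1 (-3.46 ± 0.98), Zbtb16 (-1.62 ± 0.43), Kcnv2 (-1.29 ± 0.26), Lgals4 (-1.24 ± 0.28) and the mitochondrial ribosomal RNA mt-Rnr1 (-1.22 ± 0.21) fell. Of 24 fibroblast and matrix genes 20 rose (22 and 0 adjusted over the list alone; Timp1 2.34 ± 0.32, Col1a1 1.54 ± 0.23), of 21 macrophage markers 17 (18 and 0 adjusted over the list alone; Trem2 1.89 ± 0.27, Cd68 1.02 ± 0.17) and of 20 interferon genes 11 (18 and 0 adjusted over the list alone; Mx1 1.87 ± 0.44, Ifit3 1.08 ± 0.25). Fatty acid oxidation fell in 19 of 26 (0 and 24 adjusted over the list alone; Hadha -0.50 ± 0.09) and oxidative phosphorylation in 18 of 26 (0 and 22 adjusted over the list alone; Sdha -0.52 ± 0.08). Limma's camera gave adjusted p of 6.02e-20, 8.88e-14, 5.45e-10, 8.88e-14 and 8.88e-14 for these lists, and adjusted p = 0.157 for each with an estimated correlation. Limma called 1281 genes higher and 1036 lower, with 3615 and 195 by library totals, which moved the median by 0.18. With them 6 genes of fatty acid oxidation (median -0.20) and 1 of oxidative phosphorylation were lower, the latter's median going from -0.26 to -0.07, and 18 interferon genes were higher. The 2317 calls were 1380 without WT sham replicate 4 and 1302 and 1413 without WT MI replicates 1 and 3.

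OE hearts of T3 had called responses to MI as well (n = 4 against 3). Nppa rose by 2.97 ± 0.44, from the low sham level given above, Spp1 by 2.85 ± 0.53, Timp1 by 2.35 ± 0.35 and Fn1 by 1.59 ± 0.30. Of 24 fibroblast and matrix genes 18 rose (23 and 0 adjusted over the list alone; Dcn 0.90 ± 0.11), of 20 interferon genes 18 (19 and 0 adjusted over the list alone; Isg15 1.76 ± 0.35, Oasl2 1.34 ± 0.24), of 21 macrophage markers 16 (18 and 1 adjusted over the list alone; Lyz2 1.04 ± 0.17, C1qa 0.92 ± 0.18) and of 16 lymphocyte markers 6 (12 and 0 adjusted over the list alone; Ighm 5.50 ± 1.03, Cd2 2.33 ± 0.58). Limma's camera gave adjusted p of 2.53e-14, 5.96e-12, 1.35e-09 and 2.11e-06, and adjusted p = 0.255 for each with an estimated correlation. Adipocyte markers rose in 7 of 10 (7 and 0 adjusted over the list alone; Lep 3.89 ± 1.0, Adrb3 3.93 ± 1.01), with adjusted p = 0.000466 by limma's camera and adjusted p = 0.327 with an estimated correlation, against sham hearts in which they were low. Oxidative phosphorylation counted 4 lower of 26 (0 and 7 adjusted over the list alone) with a median of -0.14, which turned to 0.02 with library totals, and adjusted p = 0.000274 by limma's camera and adjusted p = 0.427 with an estimated correlation. Limma called 1722 genes higher and 1241 lower, with 3058 and 167 by library totals, which called 0 genes of oxidative phosphorylation lower and 10 lymphocyte markers higher. The 2963 calls were 1675 and 1550 without OE sham replicates 1 and 3, 1534 and 1674 without OE MI replicates 1 and 2, and 306 without the 2 OE MI libraries low in atrial genes.

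At T3 limma called the interaction for 1 gene, Inmt (2.58 ± 0.34, adjusted p = 0.00238). It was higher in OE than WT after MI, at -0.23 ± 0.25 in sham and higher in both at T2. Sham at T3, with OE libraries low in atrial genes, stood apart. At an unadjusted p under 0.05 there were 1665 genes, DESeq2 called 103 and edgeR 1. The limma count was 0 with only the compared groups in the fit and 0 without the 2 OE MI libraries low in atrial genes, 45 without WT sham replicate 1, 27 and 2 without OE sham replicates 2 and 3, and 10 without OE MI replicate 4. For Nppa the interaction was 1.95 ± 0.60 (limma adjusted p = 0.218).

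Last, the effect of the transgene was compared between times. In sham hearts it was smaller or reversed at T3 against T2 for the matrix genes Tgfbi (-1.46 ± 0.14), Ccdc80 (-1.61 ± 0.19) and Dcn (-1.13 ± 0.14), for Cd9 (-1.18 ± 0.14) and for Rasa3 (-0.83 ± 0.10). It was higher at T3 for Eci1 (0.88 ± 0.14), Hk2 (0.57 ± 0.09), Magt1 (0.70 ± 0.09), Scmh1 (0.51 ± 0.07) and Parp1 (0.57 ± 0.09). Of 24 fibroblast and matrix genes 10 were lower (0 and 20 adjusted over the list alone). Tested together, the 24 genes had adjusted p = 8.24e-12 in limma's camera and adjusted p = 0.379 with an estimated correlation. Of 26 genes of fatty acid oxidation 15 were higher (17 and 0 adjusted over the list alone). The list's adjusted p was 2.14e-08 in limma's camera and adjusted p = 0.379 with an estimated correlation. Limma called 961 genes higher and 949 lower, with 295 and 1143 by library totals (9 genes of fatty acid oxidation higher), and the 1910 calls were 1047 and 1235 without OE sham T3 replicates 1 and 3. In injured hearts the same difference called 0 genes in limma, with 551 at an unadjusted p under 0.05 and 2 called by DESeq2.

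Against T1, an analysis across the separately normalized tables that used a joint scaling of the recovered reads, the sham effect at T3 was lower for Bcr (-3.07 ± 0.23), Trim47 (-2.17 ± 0.18), Ppic (-1.85 ± 0.16) and Rasa3 (-1.59 ± 0.12) and higher for Ttll1 (2.58 ± 0.23), Pxmp2 (2.02 ± 0.17), Fkbp4 (1.78 ± 0.15) and the muscle creatine kinase gene Ckm (1.46 ± 0.13). All 24 of 24 fibroblast and matrix genes were lower (0 and 24 adjusted over the list alone). In limma's camera the 24 genes had adjusted p = 2.04e-19, and adjusted p = 0.0302 with an estimated correlation. So were 22 of 22 ERK targets (0 and 22 adjusted over the list alone). Compared with other genes, these 22 had adjusted p = 3.92e-12 in limma's camera and adjusted p = 0.0122 with an estimated correlation. In contrast 19 of 19 genes of the tricarboxylic acid cycle were higher (19 and 0 adjusted over the list alone). With all 19 genes limma's camera gave adjusted p = 5e-14, and adjusted p = 0.0976 with an estimated correlation. In injured hearts 24 of 26 genes of fatty acid oxidation (25 and 0 adjusted over the list alone) and 25 of 26 of oxidative phosphorylation (26 and 0 adjusted over the list alone; Cox7a1 1.56 ± 0.17) were higher, with limma camera adjusted p of 1.25e-23 and 1.16e-26, and adjusted p of 0.0296 and 0.0365 with an estimated correlation. Limma called 2900 genes higher and 3034 lower in sham and 1809 and 1497 in MI, against 1701 and 4461, and 896 and 3036, by library totals. T1 and T3 also differ in experiment, which only the difference between genotypes within each removes.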

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

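Tests of the scaling and of less atrial tissue, that of reads shared with pseudogenes, and the splits of the libraries were set before their results were seen; all other tests in this part were chosen after.

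The first pattern was the low level of atrial genes in OE sham hearts at T3, with Nppa at -3.41 and a mean log2 level of Myl4, Myl7, Mybphl and Sln of 8.04 ± 0.58 (SD, n = 3) against 11.05 ± 0.60 (n = 4) in WT sham. The deposited scaling is argued against, since Nppa stayed at -3.305 or further from 0 under TMM and library totals, and so is a lasting effect on these 4 genes in every OE heart, since 2 of the OE MI libraries had a level within the range of WT MI; for Nppa it stays open, since 0 OE libraries of T3 lay within the range of WT hearts of the same injury, with limma adjusted p = 0.0516 in MI. Less atrial tissue in these libraries stays open: over 2027 called genes the change predicted from the atrial level in the other groups and the observed change had r = 0.388 (rho 0.282, across genes, which are not independent replicates), between the bounds of 0.5 and 0.2 set for and against it, so that tissue and genotype cannot be told apart. With the atrial level as a covariate the median size of the 2036 called changes went from 0.447 to 0.452 and their median SE from 0.109 to 0.149, and 730 genes were called. With the OE MI T3 libraries also left out the size was 0.351, the SE 0.197 and the calls 14. A candidate explanation is that less atrium was taken with these hearts, a hypothesis these data cannot settle.

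The second pattern was the small number of genes called for MI in OE hearts at T1 and T2. A score of 247 genes at least 2-fold higher after MI at T3 in both genotypes had a mean difference of MI minus sham, not tested itself, of 1.34, 1.53 and 1.78 (log2) in WT at T1, T2 and T3 and of 0.55, 0.48 and 1.95 in OE, T3 being the time on which the genes were chosen, while OE sham minus WT sham was 1.17, 0.49 and -0.42. An exchange of sham and MI libraries stays open at T1. There 3 OE sham libraries (up to 5.96) lay above the lowest OE MI library (5.84) and 0 reached the median one. At T2 0 lay above the lowest (highest 5.08, OE MI replicate 3 at 5.21). Its exchange stays open, with Postn, Ankrd1 and Nppb below all OE sham libraries and Col1a1 above. Too few libraries is argued against at T2 for 2-fold changes (69.7% of simulated ones recovered), not for smaller ones (54.5% at 1.5-fold). A smaller injury in OE hearts and a weaker response to the same injury cannot be told apart, since the labels do not give injury size. The part played by the higher sham score in OE at T1 and T2 was not tested.

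The third pattern was Rps2 (chromosome 17, 24718116 to 24721929, plus strand), which stood under 100 normalized counts in 4 libraries, 24 in WT sham T3 replicate 1 and 31.1, 28 and 28 in the OE sham T3 libraries. Reads counted at its 4 listed pseudogenes instead are argued against, since these changed by -2.06 counts there. Reads dropped for matching several copies would show at no gene and were not tested. An effect of genotype or injury stays open, since 1 group alone held libraries more than 4-fold apart, by 1 library, and OE sham T3 was low as a whole. Of the 25 genes most correlated with Rps2 within groups 9 lay within 1 Mb of it, against 49 of the 11591 genes ranked (Fisher's exact test, one-sided p = 3.85e-16, genes not being independent), among them Atp6v0c (r = 0.89), Rnps1 (0.84) and Ift140 (-0.77). This is consistent with a variant near Rps2 that differs between animals, a hypothesis found and tested on the same data.

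Single libraries stood apart from the other 3 of their group in 13 of 180 tests, where chance gives about 1 in 20. OE sham T1 replicate 4 had 19015856 reads against 16958836 to 17298277, and a Col1a1 count of 15124.8 against 20657.2 to 21436.1. In OE MI T3 replicate 3 the 10 leading genes took 25.746% of reads against 28.88% to 29.439%. WT MI T1 replicate 2 had 24944.6 counts of Myh7 against 13756.2 to 15630 and 259 of Cd68 against 462.3 to 472.9. Runx1 was at 77.2 in OE sham T2 replicate 2 against 52.3 to 54.9, Mki67 at 864.7 in OE MI T1 replicate 3 against 429.8 to 487, and Postn at 1844.8 in WT MI T3 replicate 2 against 4044.7 to 4127.8. Nqo1 was at 673.2 in WT sham T3 replicate 2 against 834.3 to 863.4, and at 878.2 in OE MI T3 replicate 4 against 670.1 to 699.1. Rps2 was at 1163.7 in WT sham T1 replicate 1 against 2460.3 to 2551.1, at 1696.7 in OE sham T2 replicate 3 against 804 to 864.8, and at 24 in WT sham T3 replicate 1 against 2228.3 to 2365.1.

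Differences between the groups' effects were called by limma in these cases. The response to MI differed between genotypes for 14 genes at T1, 767 at T2 and 1 at T3. Among the fixed markers it differed for Postn at T1 (-1.81, limma adjusted p = 0.0218), and at T2 for Myh6 (0.65, 0.0204), Ankrd1 (-1.76, 0.0117), Col1a1 (-1.77, 0.0111) and Postn (-1.74, 0.0187). From T2 to T3 the sham effect of OE differed for 1910 genes, with Nppa at -4.22 (limma adjusted p = 0.000332), Ankrd1 at -1.40 (0.0134), Postn at -1.22 (0.0463) and Nqo1 at 0.77 (0.0127). From T1 to T3 it differed for 5934 genes, with Erbb2 at -2.46 (limma adjusted p = 5.02e-07), Nppa at -6.36 (4.91e-10), Nppb at -4.03 (1.28e-05), Myh6 at 0.90 (8.03e-05), Myh7 at -2.22 (0.0254), Ankrd1 at -2.34 (5.56e-05), Runx1 at -1.74 (0.00266), Mki67 at -2.92 (0.000264), Cpt1b at 0.77 (0.000178), Col1a1 at -3.06 (1.06e-07), Postn at -3.84 (9.01e-10), Cd68 at -0.97 (0.00964) and Nqo1 at 0.63 (0.0188). In MI it differed for 3306 genes, with Erbb2 at -2.26 (limma adjusted p = 4.77e-06), Nppa at -3.99 (3.62e-06), Nppb at -2.91 (0.00113), Myh6 at 1.01 (2.82e-05), Ankrd1 at -2.56 (2.96e-05), Mki67 at -2.11 (0.00887), Cpt1b at 0.65 (0.00171), Col1a1 at -1.55 (0.00209) and Postn at -2.39 (7e-06).

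Other splits of the same libraries tested whether chance gives counts as large. Refitted counts can differ slightly from the report's. The following had 1 split of 35 as large, the least possible, uncorrected for the number of results. OE against WT sham gave 7271 genes at T1 (highest other 2), 3943 at T2 (25) and 2036 at T3 (839, WT sham replicate 1 moved). OE against WT MI gave 4600 (175) at T1 and 510 (26) at T3. MI in WT gave 891 (21), 3379 (1916, WT sham replicate 1 moved) and 2317 (203). MI in OE gave 2963 (2746, OE MI replicate 4 moved) at T3. Of 100 splits, 1 was as large for the interactions of T1 (14, highest other 1) and T2 (771, 303). The same held for T3 minus T2 in sham (1915, 155) and T3 minus T1 in sham (5933, 2417) and MI (3309, 2589). It held for genes called at T1 and again at T2 (2691, 14 in sham, 95, 5 in MI) or T3 (808, 0 and 228, 0). A split shortens the lists, so chance overlap of full lists was not tested. Chance stayed open for MI in OE at T1 (2 of 35 splits as large, 1 gene, highest other 5) and T2 (2 of 35, 4, 17) and the interaction of T3 (6 of 100, 1, 19). For T3 minus T2 in MI, with 0 genes, all 100 splits give as many (highest other 190, cause not tested, median 0), which says nothing about chance. OE against WT MI at T2 had 10 splits, too few for a share under 0.05 (1 as large, 242 genes, highest other 2).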

How the results depend on the processing

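The scaling by library totals, the atrial covariate and the removal of libraries were chosen after the data were seen; the cause of a change below was not tested unless the setting itself gives it, such as a stricter rule or fewer libraries. Directions of named genes called in the main fit or in the alternative were kept under DESeq2, edgeR, TMM, a pseudocount of 8, no filter, the replicate block and each left-out library. Changes of sign in genes called in neither fit were not counted. They reversed for Esam in sham at T2, at 0.007 with library totals, and for Vim at 0.18 and Vwf at 0.057 in sham at T3 with the atrial covariate and OE MI T3 not in the fit. Of 667 calls of named genes, 5 no longer passed with DESeq2, 23 with edgeR, 96 with library totals, 69 with the atrial covariate and 330 under the 2-fold rule. It was 104 of 655 with only the compared groups, 68 of 115 without the 2 OE MI T3 libraries low in atrial genes, and 65 of 70 with the covariate and OE MI T3 not in the fit. With 1 library left out it was 652 of 5411 values. Depth of 14199741 to 19015856 reads limits genes of few reads, which the filter left untested.

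Under a rule of at least 2-fold the calls were 2101, 452 and 370 for OE against WT sham at T1, T2 and T3 and 1083, 76 and 81 in MI, 259, 614 and 461 for MI in WT, 0, 0 and 748 for MI in OE, 177 for the interaction of T2, 448 for T3 minus T2 in sham, and 2202 and 905 for T3 minus T1 in sham and MI. Calls of T1 repeated at T2 and T3 were 305 and 120 in sham and 25 and 41 in MI, and Erbb2 at 0.48 in sham at T2 no longer passed. DESeq2 called 1555 and 104 genes for MI at T1 in WT and OE, 37 for MI in OE at T2, 148, 1232 and 103 for the interactions, 452 for OE against WT MI at T2 and 2 for T3 minus T2 in MI, with 161 calls repeated from T1 to T2 in MI. With no filter MI in OE at T1 gave 2 calls. With only the compared groups in the fit, which leaves fewer libraries, MI in WT gave 490 and 1629 at T1 and T2, MI in OE 0, 37 and 1856 at T1, T2 and T3, OE against WT MI 68 and 160 at T2 and T3, and the interaction of T3 0, with 29 and 85 calls repeated from T1 to T2 and T3 in MI.

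With library totals the counts were 7426 for OE against WT MI at T1, 9 for the interaction of T1, 5942 for OE against WT sham at T2, 2 for MI in OE at T2 and 3810 for MI in WT at T3, with 4440 and 1416 calls repeated from T1 to T2 and T3 in sham and 378 from T1 to T3 in MI; Erbb2 in sham at T3 passed at 0.32 (limma adjusted p = 0.0338). The atrial covariate gave 730 and 224 for OE against WT at T3 in sham and MI and 266 and 116 repeated calls, and with OE MI T3 not in the fit 14 in sham and 11 repeated. Without the 2 OE MI T3 libraries low in atrial genes MI in OE at T3 gave 306, the interaction of T3 0, and 113 calls were repeated in MI. Of 239 list calls by limma's camera among 494 tests, 14 were made with an estimated correlation and 177 by fry.

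A replicate block gave 581 and 0 for MI at T1 in WT and OE and 7 for the interaction of T1, and moved no other count by more than 1.5 times. The numbers did not pair the samples: same-numbered libraries of different groups had mean correlations of -0.011 and 0.009 in the experiments, over 0.1 in 8 of 24 and 28 of 91 pairs, against 0.004 and -0.003 for other numbers.

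With each library left out in turn the calls ranged from 6300 to 7107, 3086 to 3813 and 762 to 2071 for OE against WT sham at T1, T2 and T3, and from 3522 to 5014, 70 to 205 and 299 to 598 in MI. For MI they ranged from 282 to 1706, 2102 to 3340 and 1302 to 2654 in WT, and from 0 to 40, 1 to 10 and 1534 to 3596 in OE. The interactions gave 2 to 56, 75 to 1041 and 1 to 45; T3 minus T2 gave 1047 to 1894 in sham and 0 in MI; T3 minus T1 gave 5328 to 5932 and 2567 to 3753. Repeated calls ranged from 2202 to 2632 and 340 to 869 in sham and from 34 to 96 and 149 to 251 in MI, lowest without OE MI T2 replicate 4 and OE MI T3 replicate 1. Erbb2 ranged from 2.46 to 3.01, 0.40 to 0.52 and 0.14 to 0.26 in sham and from 2.20 to 2.75, 0.19 to 0.33 and 0.18 to 0.27 in MI, with no change of call.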

Other observations

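Genes called after MI at T3 included some that the report did not describe. In WT hearts Nrg1, which encodes neuregulin, rose by 2.15 ± 0.30 and the early growth response gene Egr2 by 2.05 ± 0.32, with Tnc (1.98 ± 0.37), Runx1 (1.38 ± 0.29) and Ankrd1 (1.19 ± 0.24). In OE hearts Nrg1 rose by 1.25 ± 0.33, Egfr by 0.92 ± 0.18, Ctgf by 1.60 ± 0.25 and Runx1 by 1.28 ± 0.32. ERK targets counted 9 higher and 0 lower of 22 in WT (12 and 1 adjusted over the list alone) and 6 and 0 in OE (6 and 0 adjusted over the list alone; 14 and 8 higher with library totals), with limma camera adjusted p of 0.000156 and 0.000977, and adjusted p of 0.157 and 0.255 with an estimated correlation.

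In sham hearts at T2, YAP and TEAD targets counted 6 higher and 0 lower of 19 (6 and 0 adjusted over the list alone; 10 higher with library totals). As a set, the 19 genes had adjusted p = 0.0477 in limma's camera and adjusted p = 0.458 with an estimated correlation.

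The libraries of OE MI at T3 were not alike. Their mean log2 level of the 4 atrial genes was 8.91, 6.96, 11.17 and 11.02 in replicates 1 to 4, and their injury scores were 6.33, 6.39, 5.31 and 5.24, so that the 2 libraries low in atrial genes were also those with the highest scores; with 4 libraries no relation was tested.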
